A study of Mus musculus with 2 samples.

How the data were processed

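The assay was chromatin immunoprecipitation followed by sequencing (ChIP-seq), in which DNA bound to a protein is pulled down with an antibody and sequenced. Per the labels' protocols, fixed cells derived from an embryonic stem cell line with a green fluorescent reporter at the Brachyury gene went into each pulldown with an anti-Flag antibody. Per the labels' protocols, single-end reads of 100 bp were sequenced on a HiSeq instrument. There were 2 libraries, 1 with doxycycline, which made Flag-tagged Hes5, and 1 without, which the labels name as the negative control. The groups were taken from the sample titles. The labels give no replicates.

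The deposited data used here were 1 peak list for the library with doxycycline, with 5 columns: chromosome, start, end, name and score. Bowtie 1.0, HOMER and the build mm9 are named in the submitters' processing notes, without their roles. The deposited peak names carry the prefix of the peak caller MACS, whose version and settings are not given in the sources used here. Whether the control library entered the peak calling is not given in those sources either. The deposited score column holds 1 score per peak as the authors' caller wrote it, and its scale is not stated in the labels. The scale was therefore examined from the values, as reported with the results. Peak positions are the authors' own. Starts were read as counted from 0 and are printed as counted from 1. The peaks were listed for a single library, so no replicate spread exists and peaks were not treated as replicates of the condition. The read depth per library is unknown, because the list holds no counts. Intervals on shares of peaks cover counting error only.

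The planned genome-based parts were not run. These were the share of peaks near gene starts, gene features, Hes binding motifs, the 14 gene lists fixed before the data were examined, and the relation of score to gene starts. The gene table at hand was for GRCm38, another build than mm9, and no mm9 sequence or annotation was used here. Coordinates were not converted between builds, the peak list carries no gene names, and so no peak was assigned to a gene. The rule fixed in advance for this case was to name the 15 peaks with the highest score, with ties ordered by width, by their coordinates.

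Peaks per chromosome were compared in complete 5 Mb bins laid from the first to the last listed peak of each chromosome, since chromosome lengths for mm9 were not used here. For each autosome and X, the mean per bin was compared with that of all other autosomes by a two-sided permutation test of bins with 100000 resamples, adjusted by Benjamini-Hochberg over 20 chromosomes. Bootstrap intervals used 10000 draws of bins. This replaced the planned comparison with chromosome length. Clustering was measured by the median distance between neighbouring peak centres and by the share of peaks with another centre within 10 kb, each against 1000 random placements of the same number of peaks over the listed span of each chromosome. Dense stretches were counted in windows of 1 Mb. Runs were defined as 5 or more peaks with steps of at most 10 kb between centres. Medians of scores were compared by two-sided permutation tests with 10000 resamples. The score scale was tested by counting scores equal, within 0.006, to -10 times the log10 of the Poisson probability of more than k reads, for a background of 1 to 8 reads, against the same backgrounds shifted by 0.1 to 0.9. The peak summary, the clustering test and the naming rule were set before the data were examined. The bins, runs, 1 Mb windows, the relation of score to width, the neighbour count of the strongest peaks and the score scale test were chosen after the list was seen.

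The methods were tested on simulated data. For uniformly placed peaks, the ratio of the median spacing to random placement was 1.02 (p = 0.114 in a permutation with 200 placements). For simulated pairs it was 0.165. An X chromosome simulated at 0.2 of the autosomal density was measured at 0.201. In that simulation peaks were placed uniformly, so it does not show how the test of bins behaves where peaks cluster, as the listed peaks do. Whole-number backgrounds were found for 100% of simulated scores made with them, and 0.952% of scores made with fractional backgrounds matched by chance. The first share was fixed in advance, because those scores were made with the same formula that the test looks up and were rounded within its tolerance. The alternatives were a stricter score threshold, leaving out sex and mitochondrial chromosomes, leaving out runs, merging close peaks, another bin size, random placement within bins, the share of peaks with a near neighbour in place of the median spacing, leaving out peaks at the highest score, another tolerance and backgrounds of 1 to 4 reads. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.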

Results

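The series mapped where the epitope-tagged transcriptional repressor Hes5 lay on the genome of mesodermal cells made from mouse embryonic stem cells. Hes5 is a basic helix-loop-helix protein and a known effector of Notch signalling. Day 3.75 embryoid bodies were the source of the cells, which were sorted for green fluorescent protein expressed from the Brachyury gene, an early mesoderm marker, and then cultured for 48 h. With doxycycline the cells made Flag-tagged Hes5, and the cells without doxycycline served as the negative control for the anti-Flag immunoprecipitation. Each condition had 1 sequencing library. The analysis rests on 1 list of 6505 peaks, which belongs to the doxycycline-treated library, and no values of the control library were analysed here. The list holds no read counts, so the read depth is unknown. No difference between the conditions could be tested, because there was 1 library per condition and no peak list for the control.

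The first question was how many peaks were listed for the anti-Flag pulldown from cells making Flag-Hes5, and how strong each was. Without values of the control library, Flag-Hes5 signal could not be told from background within the list. The 6505 peaks lay on 22 chromosomes and covered 3019 kb in total. Of these, 6451 were on the 19 autosomes, 45 on the X chromosome, 8 on the Y chromosome and 1 on the mitochondrial genome. Peaks were narrow, with a median width of 407 bp and quartiles of 340 and 540 bp. The narrowest peak spanned 146 bp and the widest 4335 bp. No pair of peaks overlapped. The score of each peak is the authors' own value from the peak caller, and its median was 247, with quartiles of 176 and 402. The lowest score was 52.3. The scores stopped at 3100, a value that 8 peaks shared, so those 8 could not be ranked among themselves by score. A score above 1000 was given to 252 peaks, which is 3.87% of the list. Stronger peaks were also wider. Across peaks, Spearman's rho between score and width was 0.52 and Pearson's r was 0.64 (permutation p = 1e-05, the smallest that 100000 resamples can give). Peaks within a list are not independent replicates, so this relation describes the list only.

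The 15 peaks with the highest scores lay on 11 chromosomes and had a median width of 986 bp. Whether any of them lies in repeated sequence was not examined, and without control values a high score need not mean Flag-Hes5 signal. All positions are given on mm9, the mouse build named in the submitters' processing notes, and their gene annotation was not analysed here. The widest peak of the list was among the 8 at the highest score, on chromosome 17 from 39979912 to 39984246. Chromosome 2 carried a pair of such peaks, from 98502353 to 98503185 and from 98506358 to 98507528. Chromosome 6 carried another pair far apart, from 86476371 to 86477348 and from 145198157 to 145199189. The other peaks at the highest score lay on chromosome 3 from 30992928 to 30994154, on chromosome 7 from 134397122 to 134398107 and on chromosome 9 from 35112764 to 35113215. Next in order came a peak on chromosome 9 from 2999972 to 3001819, with a score of 2959, which belonged to a run of 24 peaks. It was followed by a peak on chromosome 1 from 38185861 to 38186995, with a score of 2936. Chromosome 11 followed with a peak from 23206112 to 23206589 at a score of 2883. Chromosome 16 had a peak from 11143918 to 11144384 at a score of 2749. A further peak on chromosome 6, from 140571910 to 140572840, scored 2680. The remaining 2 of the 15 lay on chromosome 12 from 16901593 to 16902270, with a score of 2606, and on chromosome 4 from 46463584 to 46465569, with a score of 2446. Of these 15 peaks, 8 had another peak centre within 10 kb, against 1480 of the other 6490 peaks (Fisher's exact test, two-sided, p = 0.0099). The test treats peaks as independent, which those of one cluster, such as the pair on chromosome 2, are not, so this p is too small to be read at face value.

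The second question was whether the peaks were spread evenly over the chromosomes. The X chromosome carried few peaks. It had 1.13 ± 1.15 peaks per 5 Mb (SD, n = 31 bins), against 13.3 ± 10.7 on the autosomes (SD, n = 467 bins). This is 0.0852 times the autosomal density (95% bootstrap interval over bins 0.0562 to 0.117). The complete bins held 35 of the 45 X peaks, and the other 10 lay beyond the last complete bin. Over the whole listed span, X had 0.282 peaks per Mb, against 1.82 to 4.34 on the autosomes. A permutation test of bins gave p = 1e-05, the smallest possible, and an adjusted p of 0.0002 over the 20 chromosomes tested. The 45 X peaks made up 0.692% of the list (95% Wilson interval 0.517% to 0.924%, counting error only). The peaks present on X had a median score of 236, against 248 on the autosomes. That difference of -11.8 was of a size that random relabelling of peaks often gave (permutation p = 0.68). The test treats peaks as independent, although 8 of the 45 X peaks lay in 1 run. Of the 10 longest stretches without a peak, 6 lay on X, and the longest, of 23.6 Mb, ran from 109715279 to 133276518.

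**Figure D1:**
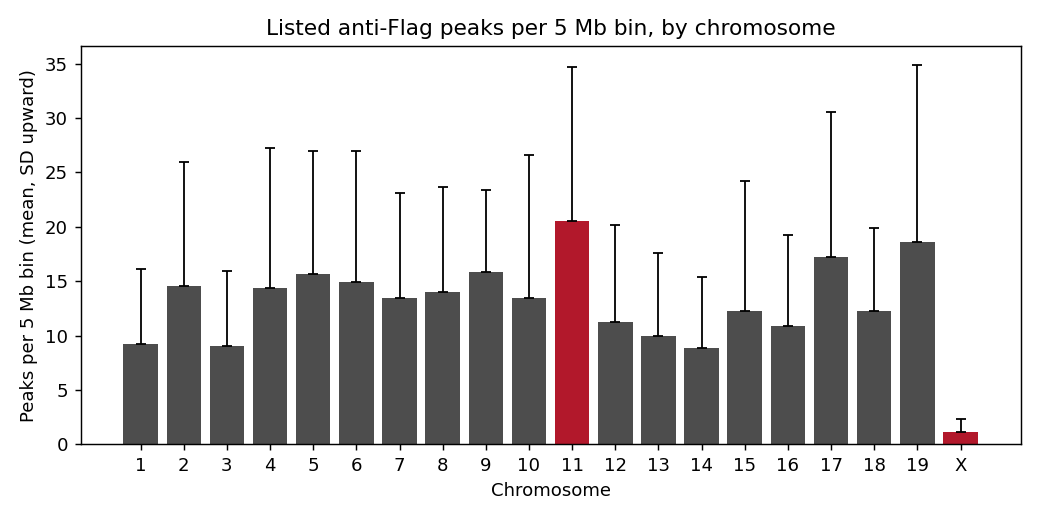
Mean number of listed anti-Flag peaks per 5 Mb bin (vertical axis) on each autosome and on X (horizontal axis), with the SD over bins drawn upward. The X chromosome, at 1.13, stands below every autosome, and chromosome 11, at 20.5, is the highest; both are drawn in red.

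Chromosome 11 was the only autosome whose density passed the test. It carried 515 peaks, or 20.5 ± 14.1 per 5 Mb (SD, n = 23 bins), which is 1.59 times the density of the other autosomes (95% bootstrap interval 1.15 to 2.07; permutation test of bins, adjusted p = 0.015). With 10 Mb bins the ratio was 1.56 and the adjusted p was 0.092, so this call was lost. The other 18 chromosomes did not pass. Chromosomes 1, 3 and 14 had the lowest autosomal ratios, 0.68, 0.67 and 0.65, with unadjusted permutation p of 0.016, 0.026 and 0.04 and adjusted p of 0.11, 0.13 and 0.16. Neighbouring bins are not independent, and the chromosome ends were taken from the first and last listed peak. The Y chromosome, whose 8 peaks all lay between 1790313 and 2886452, and the mitochondrial genome were too short in the list to be tested. The median score on Y was 102, with a highest score of 434 for the peak from 2652129 to 2652375, and the mitochondrial peak scored 58.8.

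The third question was whether peaks came in groups. Peaks lay closer together than random placement gave. The median distance between neighbouring centres was 129 kb, against a mean of 248 kb over 1000 random placements of the same number of peaks per chromosome. The random medians ran from 238 to 261 kb (permutation p = 0.001, the smallest possible). Another peak centre lay within 10 kb of 22.9% of peaks, against 5.5% at random (range 4.29% to 6.86%). A separate group of distances lay under 1 kb. Of 6483 neighbouring pairs, 814 lay within 10 kb of each other, and 507 of these lay within 1 kb. The edges of 235 pairs were at most 100 bp apart. The share of peaks with a neighbour within 10 kb rests largely on pairs within 1 kb, and was not recomputed with them merged.

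**Figure D2:**
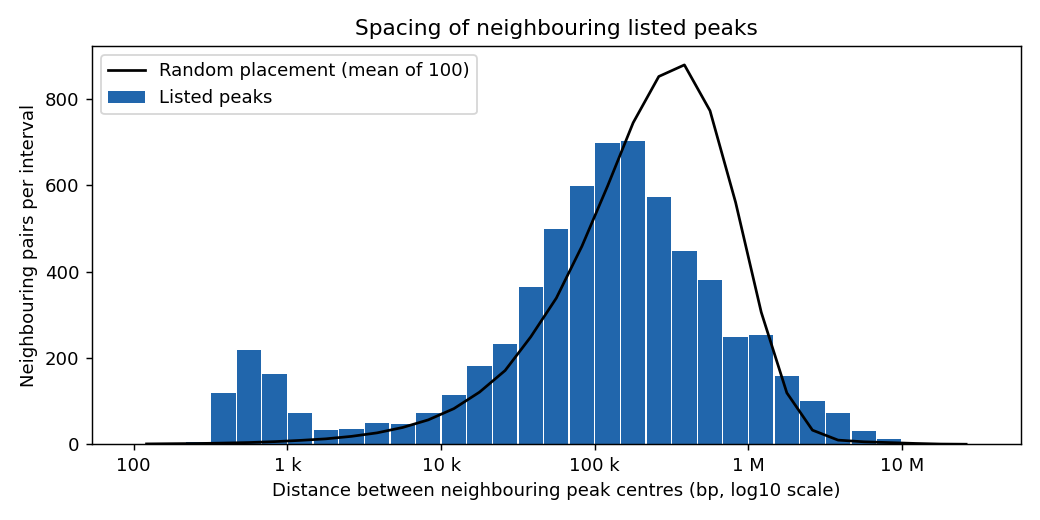
Distances between neighbouring listed peak centres (horizontal axis, bp on a log10 scale) against the number of pairs per interval (vertical axis). Bars show the listed peaks, with a separate group under 1 kb, and the line shows the mean of 100 random placements.

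Among windows of 1 Mb, the densest was on chromosome 10. The 1 Mb window from 79000001 to 80000000 held 36 peaks, and the next, from 80000001 to 81000000, held 23. The highest window in any of 1000 random placements held 15 peaks, and 8 windows of the list exceeded it. The strongest peak of the densest window ran from 79861294 to 79862303, with a score of 2183. Other dense windows held 20 peaks each on chromosome 11 from 120000001 to 121000000 and on chromosome 13 from 55000001 to 56000000. A window on chromosome 5 from 115000001 to 116000000 held 19 peaks. On chromosome 4, the window from 151000001 to 152000000 held 18. On chromosome 11, the window from 97000001 to 98000000 held 17. The remaining window was of another kind. All 24 of its peaks lay in 1 run of 38.3 kb on chromosome 9, from 2999972 to 3038316, with scores from 93.8 to 2959. A single other run of 5 or more peaks with steps of at most 10 kb was found, on X from 166424478 to 166443411. It held 8 peaks with scores from 70.6 to 1503. The 32 peaks of both runs had a median score of 272, against 247 elsewhere. Random relabelling of peaks often gave a difference of that size (permutation p = 0.45), though the test treats the neighbouring peaks of a run as independent.

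The scores themselves carried information on how they were made. Of the 6497 scores under the ceiling, 1505, or 23.2%, equalled -10 times the log10 of a Poisson tail probability with a whole-number background of 1 to 8 reads, within 0.006. Backgrounds shifted by 0.1 to 0.9 of a read gave matches for 1.06% of scores on average, and 1.49% at most over the 9 shifts. The matches were most frequent at a background of 3 reads, with 394 scores. A background of 2 reads fitted 375 scores, and 4 reads fitted 306. A background of 1 read fitted 3 scores, fewer than the 13.8 of the shifted values. For the 1502 scores with a single solution, the read number in the peak that gives the score had a median of 34 (quartiles 24 and 52). The ratio of that number to the background had a median of 10.3, with quartiles of 8 and 15. These read numbers come from solving the score and hold only for peaks that fit a whole-number background.

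**Figure D3:**
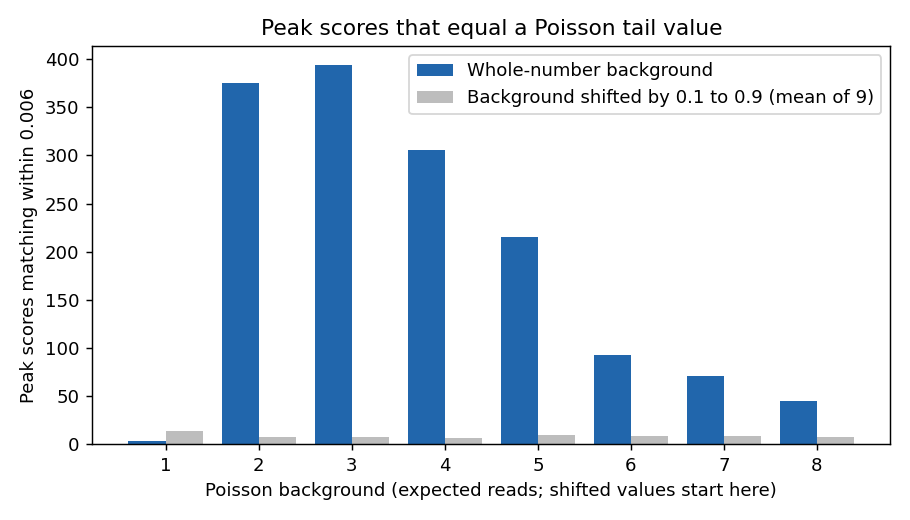
Number of peak scores (vertical axis) that equal a Poisson tail value within 0.006, for whole-number backgrounds of 1 to 8 reads (horizontal axis, blue) and for backgrounds shifted by 0.1 to 0.9 (grey, mean of 9). Backgrounds of 2 to 8 reads stand above the shifted values, and a background of 1 read does not.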

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

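For the peak number, the chromosome densities and the spacing, the stricter threshold (scores at or above the median) and leaving out sex and mitochondrial chromosomes were planned, as were, for the spacing, the share with a neighbour within 10 kb and merged centres. All alternatives for the relation of score to width and for the score scale, and leaving out runs, 10 Mb bins, placement within bins and merged edges, were chosen after seeing the data. Of 25 alternatives, 21 made no change by the criteria used. A tested result had to keep its direction and side of the threshold. A count had to stay within 1.5 times, and a share of matches within the 95% Wilson interval. Some outcomes were fixed in advance. Leaving out runs or sex and mitochondrial chromosomes removes too few peaks to move the peak number by 1.5 times. Chromosome 11 was compared with autosomes only, so leaving out sex chromosomes could not move its ratio. The number of unchanged alternatives is therefore no measure of robustness. The list held 3253 peaks at the stricter threshold, by its construction, 5928 with edges within 1 kb merged, 6473 without runs and 6451 without sex and mitochondrial chromosomes. Spearman's rho of score and width ran from 0.517, without peaks at the highest score, to 0.577, at the stricter threshold. The X chromosome had 0.0681 to 0.0867 times the autosomal density with the stricter threshold and 10 Mb bins; leaving out runs says nothing on X, whose run lies outside the bins. The spacing ratio to random placement ran from 0.522 to 0.693 over its alternatives. The share with a neighbour within 10 kb was 4.15 times that at random, and came largely from pairs within 1 kb. The higher density of chromosome 11 lost its call with 10 Mb bins (ratio 1.56, adjusted p = 0.092 in a permutation test), which leave fewer bins. Matches of scores to whole-number backgrounds fell to 20.2% among scores at or above the median and to 16.6% with backgrounds of 1 to 4 reads; for the second, fewer backgrounds were allowed, and for the first the cause was not tested. Leaving out the sex chromosomes gives no value for X. The alternatives for gene starts, gene features, motifs and gene lists were not run, since no mm9 genome or annotation was used here. No paired analysis was possible because each group has 1 library. The read depth is unknown, so sites under the caller's threshold cannot be assessed.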

Other observations

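The test of the X chromosome was chosen after the result was seen. The tests of spacing and of the runs were written before their own results, but runs and placement within bins were themselves chosen after the list was seen.

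The X chromosome carried 11.7-fold fewer peaks per 5 Mb than the autosomes. A single copy of X, as in male cells, would give fewer reads there and lower scores, roughly in proportion to depth. The list held 8 peaks on Y, so the cells may have been male, though read mapping on Y was not tested. The Y peaks had a median score of 102, against 248 on the autosomes. The median score on X was 0.952 times that on the autosomes (95% bootstrap interval 0.773 to 1.02), whereas autosomal scores divided by 2, with those under the lowest listed score left out, would give 0.516. With the lowest listed score as the only cut, halved scores would also have kept 96.9% of autosomal peaks on the list. That cut is an assumption, since the caller's settings are not given. The lowest score was 52.3 but the lower quartile 176, so few scores lay near it. Scores down to 70.6 were listed on X, so a stricter cut on score alone was not what the list shows. A filter on a value other than the score could still have kept only the stronger X peaks. The caller's filters are unknown, so the values cannot decide whether halved depth was the cause of the gap. Gene density, repeat content and read mapping on X stay open and were not tested, and the design gives no group for a biological explanation, so none was tested.

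Neighbouring peaks lay at 0.52 times the random spacing. Merging centres within 1 kb left the ratio at 0.544, with the merged median of 147 kb below the lowest random value of 259 kb. Only 507 of 6483 neighbouring pairs were that close, so merging could shift the median only slightly and could not remove the pattern. The values show that pairs within 1 kb do not set the median spacing, but cannot tell whether the caller split single enriched regions. Whether splitting accounts for the separate group of distances under 1 kb was not tested. Differences in density between large stretches explain part of the spacing. With the peak number of every 5 Mb bin kept, the ratio rose to 0.693 (observed 129 kb, lowest random value 178 kb), so those differences do not account for all of it. The placement within bins was not combined with merging of close centres, and it took no account of sequence where peaks cannot be called. Crowding of binding sites around genes stays open as a biological candidate, untested without gene positions.

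The runs on chromosome 9 from 2999972 to 3038316 and on X from 166424478 to 166443411 are candidates for signal from sequence that is present in more copies in the cells than in the assembly. Such sequence would raise the background reads too. None of the 32 scores in the runs equalled a Poisson value with a background of 1 to 8 reads, against 1505 of 6465 elsewhere (23.3%; odds ratio 0, Fisher's exact test, two-sided, p = 0.00043). This is consistent with a higher background in the runs, but it rests on 2 regions, whose neighbouring peaks the test treats as independent, and a background that is not a whole number would give the same result. A count of 0 of 32 allows a share of up to 9.38%, by counting error only. Whether the runs hold repeats was not examined.

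The Poisson values in the scores bear on a point that the labels leave open. Whole-number backgrounds of 2 to 8 reads are what counted reads of a second library, used without rescaling, would give, and fractional backgrounds would not produce them beyond the chance level. The share of matches was 23.5% with a tolerance of 0.01, and 23.3% without the runs. A candidate source is the library without doxycycline, but the scores do not name the library, and the remaining scores may rest on backgrounds averaged over wider windows.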
